A study of Trachinotus carolinus with 57 samples.

How the data were processed

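The labels describe whole-body samples of Florida pompano larvae from 9 tanks, 3 at each of 10, 20 and 30 ppt, on 7 days between days 3 and 24 post hatch. All 57 labelled libraries were used. Tanks 3, 5 and 6 were at 10 ppt, tanks 1, 2 and 7 at 20 ppt and tanks 4, 8 and 9 at 30 ppt. Tank 1 on day 6, tank 3 on days 18, 20 and 24, and tank 2 on days 20 and 24 have no library among the samples used here. The labels differ on what a library holds. The series design speaks of 1 fish per tank and timepoint, whereas the protocols speak of whole fish in numbers that varied with age and of RNA from homogenized larvae. Each library is therefore treated here as 1 sample of a tank, from an unknown number of fish. The feed abbreviations are given as the labels write them.

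Per the labels' protocols, mRNA was enriched with oligo(dT) beads, libraries were made with the NEBNext Ultra II kit, clustered on 1 flowcell lane and sequenced paired-end, and bcl2fastq 2.17 made the reads. The deposited gene and transcript tables hold raw counts from CLC Genomics, per the file names. The deposited variance-stabilised tables hold log2-scale values from DESeq2, per the file names and the labels' processing notes. The aligner settings, the genome build, the annotation and the DESeq2 version are not given in the sources used here. The gene table has 23800 genes, of which 10334 have a symbol, 12328 only a LOC number and 1138 are tRNA genes. No name was guessed for a LOC number. The transcript table has 34893 transcripts, and their counts summed to genes differed from the gene counts in 0 cells. 1444 genes had no counts.

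Gene counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test), with TMM factors (0.778 to 1.15), filterByExpr by group and 1 mean for each of the 21 salinity-by-day groups. 20194 genes were tested. P values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The biological coefficient of variation was 0.3 and the prior degrees of freedom were 4.79. Levels are counts scaled to the library total (CPM), with TMM-scaled library sizes, and log2 CPM uses a prior count of 2. Total counts ran from 4.25 to about 15 M per library. The pooled fit lends groups with 2 tanks the spread of all groups. Libraries of 1 group differed more on some days than on others, and there the pooled spread can be too small. Salinity was also tested on counts summed per tank, over days 3, 12 and 15 in all 9 tanks (20123 genes) and over days 18, 20 and 24 in the 7 tanks with a library on each of these days (20452 genes).

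Shares of the sums of squares were tested by permuting whole tanks over salinities and days within tanks. 27 gene lists were fixed by symbol before the data were examined and matched to the files exactly or with a paralog ending added or removed. The list of mitochondrially encoded genes had no member in the table and was not tested. The other lists were matched only in part, so list counts refer to matched, tested genes. Matched were 3 of 40 pancreatic enzyme genes, 5 of 20 gastric, 5 of 40 lens, 6 of 45 fast muscle, 15 of 56 liver and 47 of 54 cell cycle genes. 4 matches (acadsb, rhob, rrm2b and atf6b) were removed after the data were seen because the ending is part of another gene's name, a departure from that rule. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation) and with fry (limma). List tests for salinity within days, for 10 v 20 ppt and for the late tank sums were added after the data were seen. A list level is the mean log2 CPM of its members in a library, with the mean of the day 3 libraries set to 0.

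Named genes follow a rule written before the data were examined. They are the 10 largest rises and the 10 largest falls among called genes with a name, a mean log2 CPM above 1 and every library of one group above every library of the other, plus up to 4 members of each list described. For comparisons without calls they are the 3 genes with the smallest p. The text prints part of these, and 1 gene of the rule is not reported here. Genes of comparisons with 1 to 8 calls, and the genes of the interaction, were chosen after their values were seen.

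The test was tried on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For day 18 v 15 edgeR recovered 63 and 92 of them, for 10 v 30 ppt on day 6 it recovered 26 and 77, for 10 v 20 ppt on day 24 it recovered 9 and 60, and for the interaction 4 and 40. With 2 or 3 tanks per group a 2-fold change is thus more often missed than found.

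Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE factors, no scaling factor, no count filter, a filter of 10 counts in 9 libraries or 3 tanks, summed transcript counts, limma on the deposited variance-stabilised values, voom with the tank as a random block, the tank as a fixed block, fits of 1 day alone, libraries or tank means in place of tank sums, and leaving out each tank. Chosen after the data were seen were the mean level of the liver, intestine and pancreas lists as a covariate, leaving out 10 libraries that stand apart, and a test of the difference between days 24 and 15. The 10 libraries have a liver list level below the day 3 mean after day 6, or more than 2 log2 above it on day 6. The rule does not cover tanks 1 and 2 on day 3, whose liver levels of 2.75 and 1.65 are also high. Other rules were considered and not run. Fatty acid data named in the protocols were not used here.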

Results

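Larvae of the Florida pompano (Trachinotus carolinus) hatched at about 30 ppt and grew up in 9 tanks at 10, 20 or 30 ppt, 3 tanks at each salinity, with 30 ppt as the control. The values used here are raw gene counts of polyA RNA from whole larvae taken 3, 6, 12, 15, 18, 20 and 24 days post hatch (oligo(dT) selection, paired-end Illumina reads). The 57 libraries form 21 salinity-by-day groups, 15 with 3 tanks and 6 with 2 tanks. Total counts per library ran from 4.25 to about 15 M (median 9.58 M), and 20194 of the 23800 genes were tested. Each library is 1 tank on 1 day, so within a day the tanks are the replicates. The feed label changes with age, from GW + Rot on days 3 and 6 to MF on day 24. Age and feed therefore cannot be separated here, except between days 3 and 6 and between days 18 and 20. Changes are given as log2 fold change ± SE and levels as mean counts scaled to the library total (CPM) ± SD.

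Age carried most of the variation and salinity little of it. Day accounted for 54.3% of the sums of squares of log2 CPM over all tested genes (permutation p = 1.0e-04, the smallest possible with the number of permutations drawn, within tanks; highest permuted share 27.4%). Salinity accounted for 2.44% (exact p = 0.346 over all assignments of the 9 tanks to salinities; median of the other assignments 1.99%), and the interaction of the 2 for 13.9%. The first principal component held 51.3% of the variance and went from −103 ± 20.1 on day 3 (n = 9) to 83.2 ± 8.54 on day 18 (n = 8) and 105 ± 11 on day 20 (n = 7). On day 24 it was 31.1 ± 59.6 (n = 7).

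From day 3 to day 24 the largest rises were in genes of the acid-secreting stomach. The subunits of the gastric proton pump, atp4a and atp4b, rose by 7.19 ± 0.70 and 8.19 ± 0.92, and pgc, which codes for a pepsinogen, rose by 7.50 ± 0.89. atp4a went from 0.538 ± 0.194 CPM (n = 9) to 84.2 ± 68.8 CPM (n = 7). The pancreatic proteases ctrl and cpb1 rose by 5.51 ± 0.61 and 4.36 ± 0.50. The skeletal matrix genes mgp, col10a1 and bglap rose by 5.80 ± 0.34, 5.59 ± 0.43 and 5.53 ± 0.60, and the photoreceptor genes guca1b and pde6b by 5.70 ± 0.31 and 5.53 ± 0.47. The cholinergic modulator lynx1 rose by 6.73 ± 0.64. Among the largest falls were the organic anion transporter slc22a7 (−5.50 ± 0.59), cystm1 (−4.79 ± 0.36) and the transcription factor pax8 (−3.47 ± 0.31). For each of these genes except cpb1 every library of one day lay above every library of the other. cpb1 is named as a member of a fixed list, as are the genes of the next paragraph.

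Muscle and innate immune genes rose over the same span, as did single lymphocyte, myelin and lipid genes. In muscle these were myoglobin (mb, 5.51 ± 0.55), myoz1 of the Z-disc (2.72 ± 0.22) and the fast light chain mylpf (1.96 ± 0.21). The lymphocyte genes lck (4.05 ± 0.39), cd74 (3.42 ± 0.34) and rag1 (3.30 ± 0.63), the macrophage gene mpeg1 (4.74 ± 0.63), the myelin genes mpz (3.91 ± 0.34) and mbp (3.25 ± 0.35) and fatty acid synthase, fasn (2.82 ± 0.21), rose as well. Among ion and osmolyte genes, the glutamate transporter slc1a3 (5.24 ± 0.44), the sodium-proton exchanger slc9a3 (2.56 ± 0.36) and the chloride channel cftr (2.15 ± 0.38) rose, and the potassium channel kcnj1 fell (−2.57 ± 0.41). The lens gene bfsp2 (−2.63 ± 0.52), the crystallin cryba2 (−1.77 ± 0.44), the pteridine gene pts (−2.26 ± 0.21) and the melanocyte channel trpm1 (−2.75 ± 0.29) fell.

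edgeR called 11615 genes between day 24 and day 3 (5700 higher and 5915 lower on day 24, adjusted p < 0.05, 7 and 9 libraries). Members of fixed lists called were bone and cartilage 17 higher and 3 lower of 22 (median log2 2.34, camera adjusted p = 2.16e-05) and fast muscle 6 higher of 6 (2.09, 4.54e-05). Innate immunity had 17 higher and 2 lower of 25 (1.64, 0.0017), pancreatic enzymes 3 higher of 3 (4.36, 0.00855) and osmolytes 9 higher and 1 lower of 15 (0.62, 0.016). Pigment cells had 1 higher and 11 lower of 19 (−0.62, 0.016) and lens crystallins 5 lower of 5 (−1.77, 0.0381). Adjusted over the list alone the counts were the same, apart from 10 higher for osmolytes and 18 higher for innate immunity. Camera lost all 7 calls with an estimated correlation (adjusted p = 0.404 to 0.509). Adaptive immunity (7 higher, 3 lower of 13), the gastric list (3 higher, 1 lower of 5), eye and phototransduction (8 higher, 4 lower of 16), endocrine axes (7 higher, 3 lower of 16) and ion transport (7 higher, 4 lower of 16) had called members without a camera call (adjusted p = 0.284, 0.293, 0.148, 0.313 and 0.408). The neural list, with 7 higher and 10 lower of 23 and a median of −0.29, had no camera call either (adjusted p = 0.927). With the mean level of the liver, intestine and pancreas lists as a covariate, a choice made after the data were seen, 7052 genes were called.

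**Figure D1:**
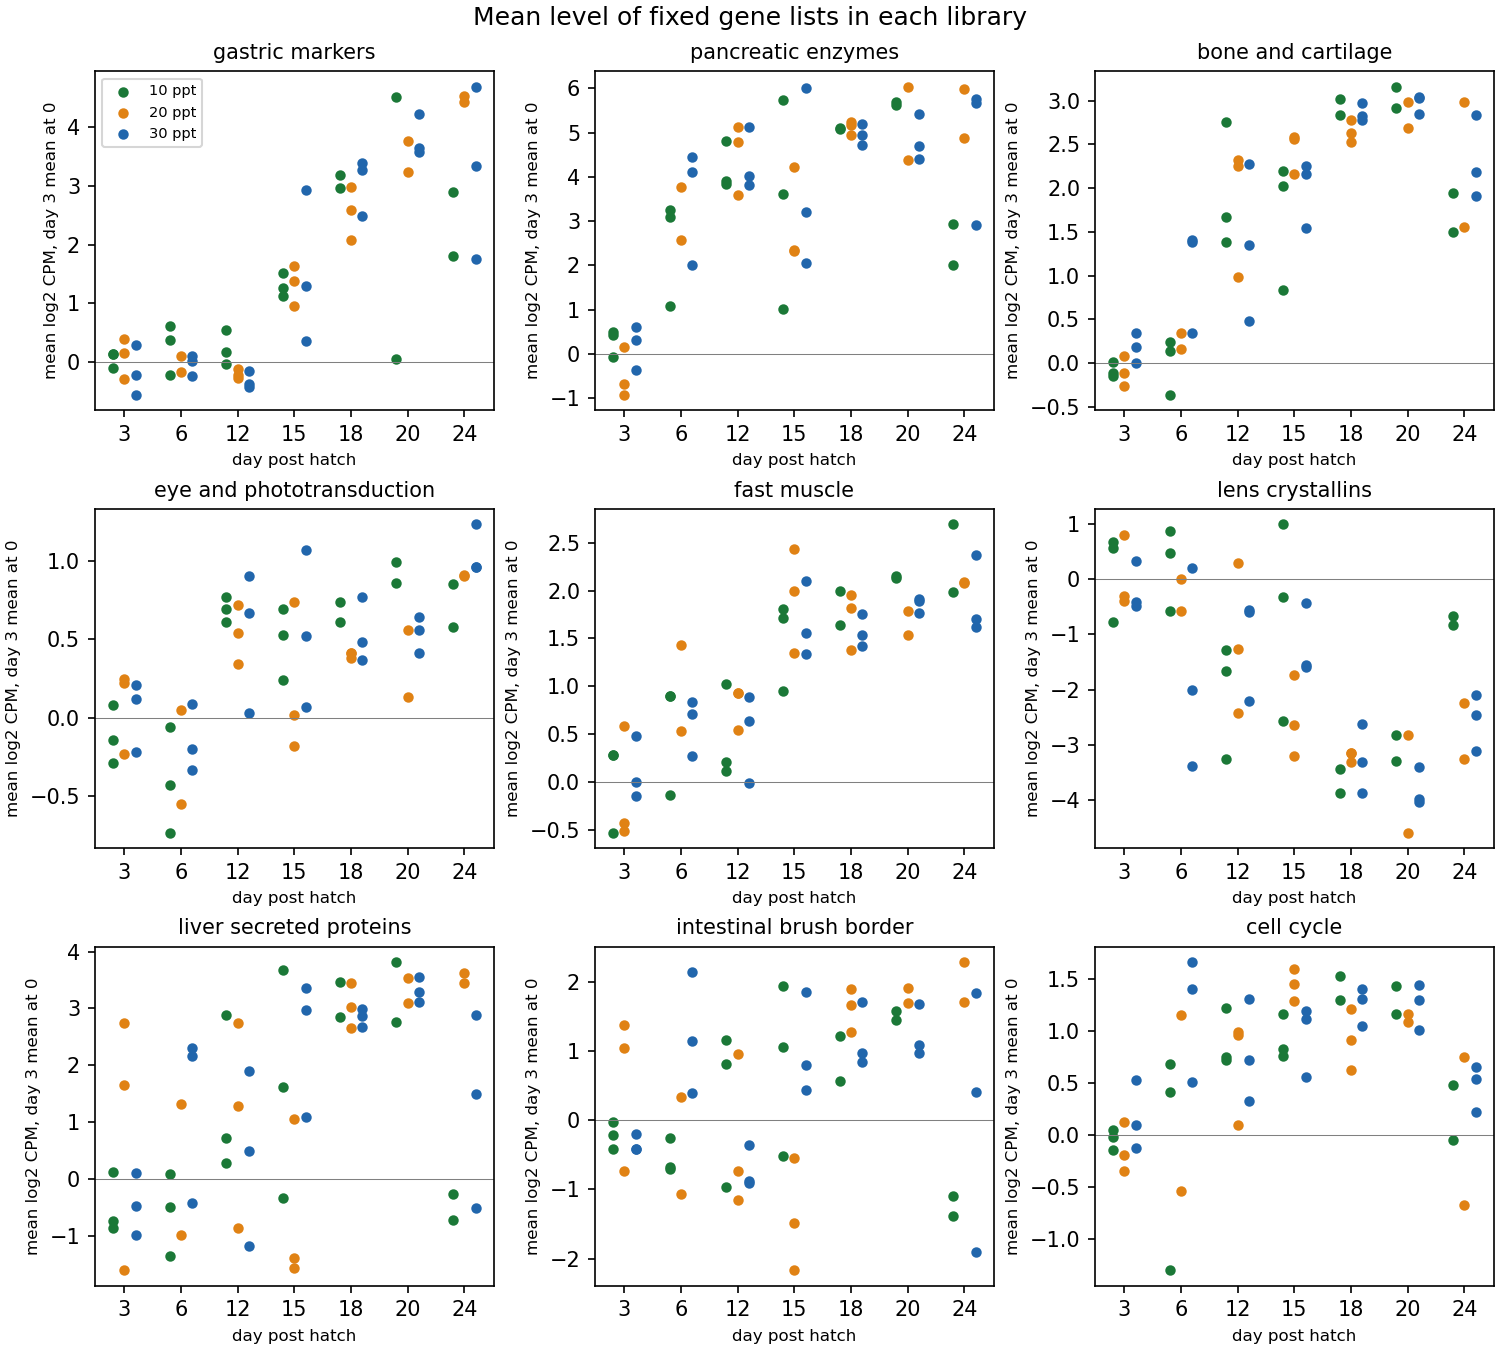
Mean log2 CPM of 9 fixed gene lists in each of the 57 libraries, with the mean of the 9 day 3 libraries set to 0. Each point is 1 tank on 1 day and colours give the salinity.

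From day 3 to day 6, under the same feed label, the pancreatic proteases rose first. ctrl rose by 3.50 ± 0.56, cpb1 by 3.24 ± 0.47 and cpa1 by 2.92 ± 0.52, and cpb1 reached 751 ± 419 CPM (n = 8) from 80.8 ± 34.9 CPM (n = 9). The carotenoid-cleaving enzyme bco2 (3.56 ± 0.53), the egg membrane homologue vmo1 (2.70 ± 0.35), the monocarboxylate transporter slc16a1 (2.16 ± 0.28) and the circadian gene clock (1.95 ± 0.19) were among the largest rises. The glucose gene gck (2.38 ± 0.53) and the lipid gene fasn (1.66 ± 0.20) rose too. So did the myelin genes mpz (2.31 ± 0.32) and mbp (2.22 ± 0.33), the muscle gene actn3 (1.15 ± 0.26), the chaperones hspb1 (1.27 ± 0.16) and hspa5 (1.16 ± 0.24) and the replication genes tyms (1.47 ± 0.27) and pcna (1.09 ± 0.23). The autophagy gene tp53inp2 (−1.98 ± 0.14), the lipase inhibitor angptl4 (−1.84 ± 0.16), klf11 (−1.80 ± 0.18), agr2 of mucous cells (−1.77 ± 0.25), the lipoprotein receptor scarb1 (−2.06 ± 0.37) and pts (−1.32 ± 0.19) fell.

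4849 genes were called between days 6 and 3 (2555 higher and 2294 lower on day 6). Fixed lists that camera called were pancreatic enzymes 3 higher of 3 (camera adjusted p = 0.000321) and cell cycle 25 higher of 47 (26 adjusted over the list alone, median log2 0.67, 5.87e-05). Also called were stress genes 10 higher and 2 lower of 27 (10 and 3, 0.00247), fast muscle 4 higher of 6 (5 higher, 0.00719) and pigment cells 5 lower of 19 (5, 0.00553). Cholesterol synthesis (5 higher of 19, 6 adjusted over the list alone, 0.0455) and carbohydrate metabolism (5 higher of 17, 7 adjusted over the list alone, 0.0457) were at the edge of the threshold. None of the 7 was called with an estimated correlation (adjusted p = 0.209 to 0.871). The cell cycle level of 1.4 and 1.66 (log2 over the day 3 mean) in tanks 8 and 9 at 30 ppt was the highest of day 6, where the other 6 libraries had −1.3 to 1.15. The count was 2692 without tank 7 and 1960 without the 10 libraries that stand apart by their liver gene level (a choice made after the data were seen).

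From day 6 to day 12 cartilage and photoreceptor genes rose. The cartilage genes matn3 (3.83 ± 0.36), col10a1 (3.61 ± 0.42), acan (2.36 ± 0.29) and mgp (2.36 ± 0.29) and the tendon gene tnmd (3.07 ± 0.34) rose, with matn3 going from 1.27 ± 0.696 CPM (n = 8) to 18.3 ± 8.35 CPM (n = 9). The rod genes guca1b (3.57 ± 0.31), pde6g (2.93 ± 0.28), pde6b (3.07 ± 0.50) and rbp3 (1.99 ± 0.35) rose, as did lynx1 (4.37 ± 0.63) and the neuronal growth genes dcx (0.74 ± 0.22) and gap43 (0.72 ± 0.23). Cholesterol genes (fdps 1.18 ± 0.32, sqle 1.35 ± 0.42) and haem genes (fech 0.75 ± 0.12, cpox 0.65 ± 0.17) rose by less. The acid phosphatase acp5 (−3.05 ± 0.47), tmem159 (−2.98 ± 0.30), cystm1 (−2.94 ± 0.32), the macrophage and pigment cell receptor csf1r (−1.41 ± 0.18) and the melanin gene dct (−0.93 ± 0.22) fell. The kidney-type transporters kcnj1 (−1.39 ± 0.34) and slc12a1 (−1.43 ± 0.43) fell with them.

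2791 genes were called (1339 higher and 1452 lower on day 12). Bone and cartilage had 15 higher and 1 lower of 22 (17 and 2 adjusted over the list alone, median log2 1.67, camera adjusted p = 5.82e-10) and eye and phototransduction 8 higher and 2 lower of 16 (9 and 3, 0.78, 0.000235). Cholesterol synthesis had 5 higher of 19 (9, 0.74, 0.000138) and the erythroid list 2 higher of 7 (4, 0.39, 0.00875). Pigment cells had 1 higher and 4 lower of 19 (2 and 6, 0.00875), the neural list 4 higher of 23 (4, 0.0175) and the cell cycle list only 1 of 47 (0, 0.00113). Camera gave adjusted p = 0.168 with an estimated correlation for the bone, eye and erythroid lists and 0.376 to 0.676 for the other 4. Without tank 9 the count was 1811, and without the 10 libraries that stand apart it was 4437.

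From day 12 to day 15, when the feed label changed from GW+Art+EArt to Art+EArt+MF, fast muscle and gastric genes rose. myoz1 rose by 1.42 ± 0.20, actn3 by 1.33 ± 0.26, trdn of the calcium release complex by 1.54 ± 0.19 and nexn by 1.18 ± 0.16. The gastric genes atp4a (3.42 ± 0.65), atp4b (3.98 ± 0.82) and pgc (4.32 ± 1.26) rose for the first time between sampled days. bglap of bone (1.87 ± 0.49) and the retinoid isomerase rpe65 (1.67 ± 0.33, from 7.00 ± 2.73 to 22.6 ± 7.38 CPM, n = 9 and 9) rose too. Energy genes rose, with hadh at 1.02 ± 0.15, hadhb at 0.90 ± 0.16, gapdh at 1.44 ± 0.33 and pgk1 at 0.73 ± 0.17. Also up were hspb8 (0.96 ± 0.19), sod2 (0.69 ± 0.11) and the salt cotransporters slc12a1 (1.72 ± 0.42) and slc12a3 (1.56 ± 0.41). The Purkinje cell gene pcp2 (−1.97 ± 0.28), slc4a3 (−1.33 ± 0.26), the cone channel cnga3 (−1.12 ± 0.26) and gad2 of inhibitory neurons (−0.87 ± 0.24) fell.

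3213 genes were called (1397 higher and 1816 lower on day 15). Fast muscle had 6 higher of 6 (6 adjusted over the list alone, median log2 1.2, camera adjusted p = 5.87e-07), fatty acid oxidation 11 higher of 23 (13, 0.53, 3.03e-09) and carbohydrate metabolism 3 higher of 17 (6, 0.45, 0.00901). Stress genes had 5 higher of 27 (5, 0.0382), the neural list 1 higher and 4 lower of 23 (1 and 7, 0.0475) and the cell cycle list 1 higher of 47 (0, 0.000487). The gastric list, with 3 higher and 1 lower of 5, was not called by camera (adjusted p = 0.404). With an estimated correlation the adjusted p was 0.135 for fast muscle, 0.482 for fatty acid oxidation and stress, 0.645 for carbohydrate metabolism and 0.906 for the other 2. The count was 1839 without tank 2, 5176 with the visceral covariate and 597 without the 10 libraries that stand apart.

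From day 15 to day 18 immune, matrix, liver and skin genes rose, and lens and neural genes fell. Myoglobin (mb) rose by 3.45 ± 0.48, the neutrophil receptor csf3r by 2.60 ± 0.49, the macrophage receptors mrc1, stab1 and marco by 2.29 ± 0.47, 2.09 ± 0.40 and 1.5 ± 0.33, scara5 by 2.44 ± 0.51 and the antigen presentation gene cd74 by 1.56 ± 0.30. In matrix and bone these were lum (2.04 ± 0.48), aspn (1.96 ± 0.39), col10a1 (1.55 ± 0.35) and runx2 (1.4 ± 0.33), in liver rbp4 (1.22 ± 0.35) and apob (1.93 ± 0.61), and in skin tp63 (0.83 ± 0.25) and dsp (0.72 ± 0.22). The lipid genes sc5d (1.45 ± 0.44) and pparg (1.0 ± 0.27) rose as well. The crystallins crybb1 (−2.34 ± 0.44) and cryba4 (−2.33 ± 0.43), npy (−1.88 ± 0.36) and the neuronal genes slc17a6 (−1.51 ± 0.28), stmn2 (−1.43 ± 0.29) and gap43 (−1.22 ± 0.23) fell. mb went from 0.741 ± 0.759 CPM (n = 9) to 5.69 ± 1.65 CPM (n = 8), and crybb1 from 2490 ± 2680 to 421 ± 109 CPM.

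8661 genes were called (4288 higher and 4373 lower on day 18). Innate immunity had 17 higher of 25 (20 adjusted over the list alone, median log2 1.22, camera adjusted p = 2.79e-06) and bone and cartilage 12 of 22 (12, 0.67, 0.00214). Skin had 7 of 10 (10, 0.72, 0.00214), liver secreted proteins 7 of 15 (7, 1.28, 0.000599) and cholesterol synthesis 6 of 19 (6, 0.54, 0.00671). Fatty acid oxidation had 10 higher and 1 lower of 23 (12 and 1, 0.012), the intestinal brush border 4 higher of 12 (4, 0.038) and osmolytes 6 higher and 1 lower of 15 (6 and 1, 0.038). Lens crystallins had 5 lower of 5 (5, −2.23, 0.000599) and the neural list 2 higher and 15 lower of 23 (2 and 16, −0.73, 0.000278). With an estimated correlation the adjusted p of these 10 lists was 0.542 to 0.567. Liver levels on days 18 and 20 lay within 2.65 to 3.81 (log2 over the day 3 mean) in all 15 libraries, whereas on day 15 they ran from −1.56 in tank 2 to 3.67 in tank 3. The count was 4457 without tank 5, 5175 without the 10 libraries that stand apart and 542 with the visceral covariate.

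Days 18 and 20 hardly differed. Under the same feed label 3 genes passed, LOC111220555 (1.6 ± 0.31), LOC111226139 (−1.77 ± 0.34) and LOC111227671 (3.64 ± 0.71), the last with 1 library at 253 CPM. edgeR gave 1475 genes at unadjusted p < 0.05, DESeq2 called 6 genes and the fit with a replicate block called 0.

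From day 20 to day 24, when only MF remained on the label, sterol, replication, lipid and liver genes fell and neural genes rose. The sterol enzymes ebp (−2.96 ± 0.51), mvd (−2.67 ± 0.38), fdps (−2.53 ± 0.36), sqle (−2.3 ± 0.46) and dhcr7 (−2.25 ± 0.48) fell, with ebp going from 37.6 ± 14.6 to 4.84 ± 3.68 CPM (n = 7 and 7). The replication genes e2f7 (−2.06 ± 0.47), gins2 (−1.79 ± 0.39) and mcm2 (−1.62 ± 0.33) fell. So did the fatty acid enzymes fasn (−1.29 ± 0.22), cpt2 (−1.0 ± 0.20) and acads (−1.0 ± 0.21), the plasma protein genes hpx (−2.52 ± 0.77) and ttr (−2.04 ± 0.65) and the chylomicron genes mttp (−1.53 ± 0.39) and apoa4 (−1.61 ± 0.46). The endoplasmic reticulum chaperones hspa5 (−1.57 ± 0.27) and hsp90b1 (−1.54 ± 0.28) and the bone gene entpd5 (−1.73 ± 0.47) fell too. The stress-induced genes ddit4 (1.72 ± 0.31) and ddit3 (1.37 ± 0.25), the muscle ubiquitin ligase fbxo32 (3.34 ± 0.69), armc2 (2.1 ± 0.37), the histone methyltransferase ezh1 (1.84 ± 0.30), the synaptic genes snap25 (1.49 ± 0.30) and syt1 (1.35 ± 0.26) and crybb1 (1.61 ± 0.47) rose.

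8183 genes were called (4472 higher and 3711 lower on day 24). Cholesterol synthesis had 17 lower of 19 (17 adjusted over the list alone, median log2 −1.94, camera adjusted p = 2.53e-10) and the cell cycle 39 lower of 47 (41, −0.89, 1.35e-12). Fatty acid oxidation had 17 lower of 23 (18, −0.60, 1.96e-07), liver secreted proteins 10 lower of 15 (13, −1.81, 0.000813) and fatty acid synthesis 7 lower and 1 higher of 12 (7 and 1, −0.76, 0.00214). Bone and cartilage had 8 lower of 22 (8, 0.00085), the intestinal brush border 4 lower of 12 (4, 0.00587), carbohydrate metabolism 5 lower and 1 higher of 17 (5 and 1, 0.0247) and innate immunity 9 lower and 1 higher of 25 (9 and 1, 0.0247). The neural list had 19 higher of 23 (19, 1.16, 3.03e-08) and lens crystallins 4 higher of 5 (5, 1.53, 0.0197). With an estimated correlation the adjusted p of these 11 lists was 0.552 to 0.582. On day 24 the liver level was −0.71, −0.26 and −0.51 in tanks 5, 6 and 8 and 1.5 to 3.63 in tanks 1, 4, 7 and 9, and the neural level was 0.74, 0.54 and 0.78 against −0.74 to 0.15. The count was 3728 without tank 7, 3641 with the visceral covariate and 2728 without the 10 libraries that stand apart.

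Within 30 ppt alone, with 3 tanks on each day, single genes of pancreas, cartilage, photoreceptors and stomach rose as well, and no list was tested. From day 3 to day 24 ctrl rose by 6.65 ± 1.09, guca1b by 6.11 ± 0.53 and col10a1 by 5.78 ± 0.73, and slc22a7 (−5.80 ± 0.91) and cystm1 (−5.28 ± 0.54) fell. Step by step, ctrl (4.13 ± 0.97) rose and tp53inp2 (−2.3 ± 0.23) and fbxo25 (−3.77 ± 0.49) fell by day 6, and matn3 (4.06 ± 0.60) and pde6g (3.07 ± 0.46) rose and the glucose transporter slc5a1 (−3.20 ± 0.70) fell by day 12. By day 15 atp4a (4.57 ± 1.19) rose and pcp2 (−2.47 ± 0.48) fell. By day 18 mb (4.59 ± 0.88), mrc1 (3.13 ± 0.83) and cilp (2.3 ± 0.59) rose. By day 24 mvd (−3.03 ± 0.58), fdps (−2.90 ± 0.55) and aacs (−2.43 ± 0.39) fell and fosb (2.84 ± 0.58) rose. Called were 6686 genes for day 24 v 3 and, in order of age, 5638, 688, 1743, 763, 0 and 2438 for the 6 steps. For day 20 v 18 edgeR gave 240 genes at unadjusted p < 0.05 and DESeq2 called 1. DESeq2 called 1165 genes for day 12 v 6 and 1991 for day 18 v 15, and the fit with a replicate block 189 for day 18 v 15. Leaving out 1 tank lowered the counts to 1901 for day 24 v 3 (without tank 4), 209, 58 and 0 for the first 3 steps (without tank 9) and 0 for day 18 v 15 and day 24 v 20 (without tank 8). Without the 10 libraries that stand apart the first 3 steps had 12, 35 and 60 calls, the step from 15 to 18 had 1979 and the last step 638.

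Over tank sums of days 3, 12 and 15 edgeR called no gene between salinities, and DESeq2 at most 23 for a pair of salinities and 30 for the trend. For ion transport 16 of 70 fixed genes were matched, for osmolytes 15 of 38, and for claudins, tight junctions and aquaporins 7 of 65. Of these matched genes 0 were called for 10 v 30 ppt, with median log2 changes of 0.00, 0.08 and −0.01. The unmatched genes of these lists were not tested by name. The smallest p belonged to LOC111230176, which followed the salinity with 1.26 ± 0.371 CPM at 10 ppt, 3.33 ± 0.634 at 20 ppt and 5.71 ± 0.321 at 30 ppt (n = 3 tanks each). Its 10 v 30 ppt change was −2.20 ± 0.25 (edgeR adjusted p = 0.231, all 3 tanks lower). edgeR called 0 genes for 10 v 30, 20 v 30 and 10 v 20 ppt and for the trend over salinity, with 564, 478, 487 and 644 genes at unadjusted p < 0.05. Each of these counts is below the share of 0.05 of the 20123 tested genes that would pass with no difference at all. DESeq2 called 23, 1, 3 and 30 genes. In data simulated with 3 tanks per group and no tank effect, this test recovered 40 of 100 genes changed 2-fold and 84 of 100 changed 4-fold. camera called 3 lists for 10 v 30, 4 for 20 v 30 and 6 for 10 v 20 ppt, and 0 with an estimated correlation.

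**Figure D2:**
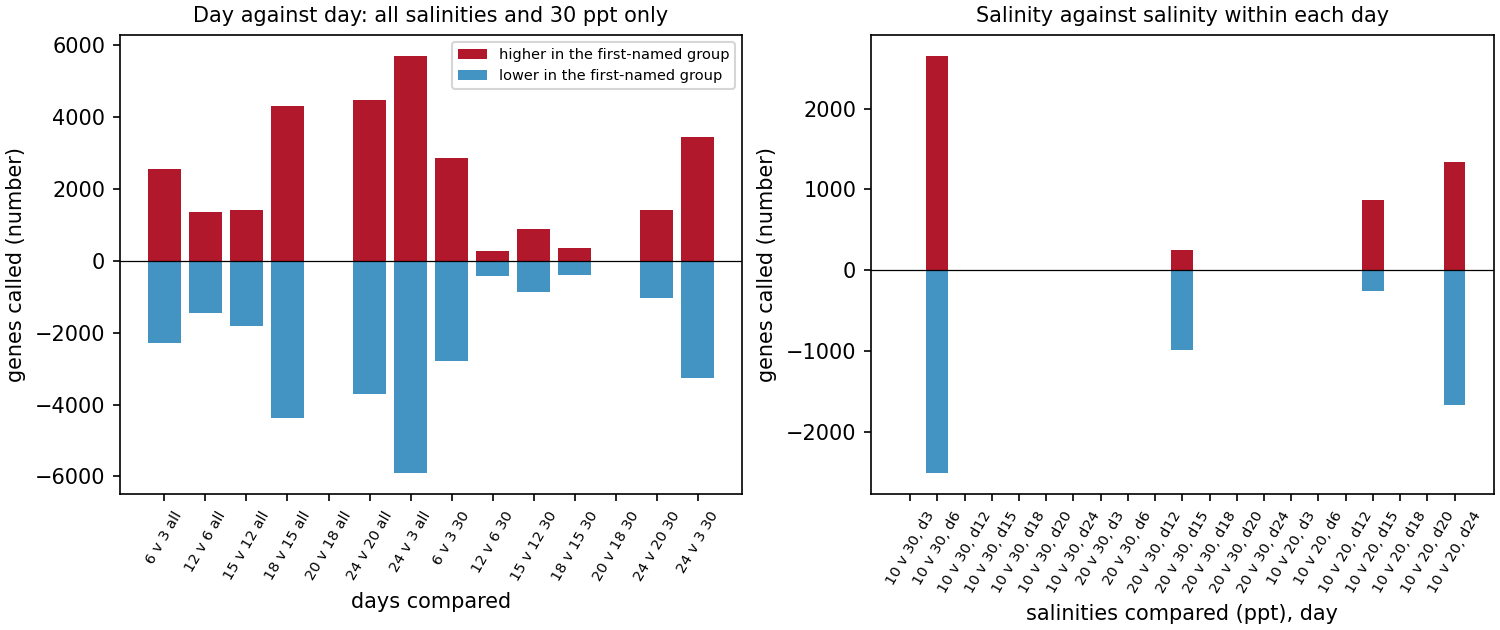
Number of genes called by edgeR at adjusted p < 0.05 for each day comparison (left) and each salinity comparison within a day (right). Bars above 0 are genes higher in the first-named group.

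Within single days most salinity comparisons had no or few called genes. On days 3, 12 and 18 edgeR called 0 genes for all 3 pairs of salinities (unadjusted p < 0.05: 658, 898 and 1029 genes on day 3, 517, 272 and 420 on day 12, and 170, 205 and 384 on day 18, in the order 10 v 30, 20 v 30 and 10 v 20 ppt). With no difference at all, a share of 0.05 of the 20194 tested genes would pass unadjusted. All of these counts but the 1029 lie below that share. DESeq2 called 4, 2 and 1 genes on day 3, 0 on day 12 and 1, 0 and 0 on day 18. On day 20 LOC111227671 alone passed, for 10 v 30 ppt (7.42 ± 1.07) and for 10 v 20 ppt (6.92 ± 1.25), from 1 of 2 libraries at 253 CPM and the other at 1.38 CPM. For 20 v 30 ppt on day 20 edgeR called 0 genes (110 at unadjusted p < 0.05) and DESeq2 1. On day 15 8 genes, all known only by number, were lower at 10 than at 30 ppt, among them LOC111230176 (−2.87 ± 0.55, 1.17 against 8.46 CPM) and LOC111224968 (−4.61 ± 0.78, 10.6 against 250 CPM), in all 3 tanks each. That count ran from 0 to 76 when 1 tank was left out. On day 24 LOC111228998 was lower at 10 than at 30 ppt (−3.61 ± 0.64, 2 and 3 tanks). At unadjusted p < 0.05 there were 1277 genes for 10 v 30 ppt on day 15 and 3128 on day 24.

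On day 6 larvae at 10 ppt had less RNA of sterol, cell cycle, cartilage, gut and liver genes than larvae at 30 ppt, and more of neural genes. Among the largest falls were tmigd1 (−4.63 ± 1.2) and mamdc4 (−4.38 ± 1.21) of absorptive epithelia, the protease adamts17 (−4.02 ± 0.95) and the ascorbate transporter slc23a1 (−3.81 ± 1.18). Lower at 10 ppt were also the sterol genes dhcr7 (−2.96 ± 0.75) and insig1 (−1.96 ± 0.53), and mcm2 (−2.25 ± 0.51) and rpa1 (−2.18 ± 0.50) of replication. The same held for col9a2 (−2.31 ± 0.68) and matn4 (−1.85 ± 0.48) of cartilage, cdx1 (−3.69 ± 1.04), slc5a1 (−2.37 ± 0.68) and cubn (−2.95 ± 0.87) of the intestine, and hpx (−3.36 ± 1.21) and apob (−3.10 ± 1.13) of the liver. Of the salt transporters slc12a2 (−2.39 ± 0.51), slc12a1 (−3.12 ± 0.74) and cftr (−2.92 ± 0.66) were lower. So were csad (−2.19 ± 0.62) and isyna1 (−0.88 ± 0.25), which make taurine and inositol, the glucose genes pygl (−3.34 ± 0.72) and gck (−3.50 ± 0.86), hadha (−1.44 ± 0.39) and dsp of skin (−1.2 ± 0.37). Higher at 10 ppt were armc2 (2.62 ± 0.55), fbxo25 (2.59 ± 0.48), gnrh2 (2.07 ± 0.66), fosb (1.93 ± 0.55), syt1 (1.39 ± 0.39), elavl3 (1.54 ± 0.47), ddit4 (1.83 ± 0.46) and ddit3 (1.73 ± 0.38).

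edgeR called 5169 genes (2655 higher and 2514 lower at 10 ppt, 3 tanks each). Cholesterol synthesis had 13 lower of 19 (17 adjusted over the list alone, median log2 −1.67, camera adjusted p = 3.43e-06), the cell cycle 27 lower of 47 (31, −1.17, 3.99e-12) and bone and cartilage 10 lower of 22 (11, −1.13, 0.00288). Intestine had 7 lower of 12 (10, −2.12, 0.00473), liver 3 lower of 15 (11, −2.39, 0.00727) and osmolytes 7 lower of 15 (8, −0.88, 0.00713). Fatty acid oxidation had 7 lower of 23 (10, −0.71, 0.000132), carbohydrate metabolism 6 lower of 17 (8, −0.84, 0.00288), skin 6 lower of 10 (6, −1.05, 0.00367) and the neural list 5 higher of 23 (5, 0.65, 0.00288). Lens crystallins had 0 called of 5 (0, 1.46, 0.0178), and ion transport, with 5 lower and 1 higher of 16 (6 and 3), was not called by camera (adjusted p = 0.302). The adjusted p of the 11 lists with an estimated correlation was 0.609 to 0.696. With fry, cholesterol synthesis, the cell cycle, osmolytes and carbohydrate metabolism were called (adjusted p = 0.0224 each), and so was the list of claudins, tight junctions and aquaporins (0.0224). Not called by fry were skin, fatty acid oxidation and lens crystallins (0.0575 each), the neural list (0.0681), bone and cartilage (0.0692), intestine (0.0698) and liver (0.211). In the liver, bone, lens, sterol and cell cycle lists the difference came mainly from 2 of the 3 libraries at 30 ppt, tanks 8 and 9. Liver levels were 2.3 and 2.16 against −1.35 to 1.33 in the other 6 libraries of the day, bone 1.41 and 1.39 against −0.36 to 0.35, and lens −2.01 and −3.39 against −0.58 to 0.88. The third tank at 30 ppt, tank 4, had a liver level of −0.41, and its cholesterol and cell cycle levels (0.47 and 0.51) lay below those of tank 6 at 10 ppt (0.56 and 0.68). The lowest cell cycle level was that of tank 3 at 10 ppt (−1.3). For tank 4 the levels of ion transport (0.25), osmolytes (0.35), intestine (0.39) and skin (0.57) lay above those of the 3 tanks at 10 ppt, close to those of tank 2 at 20 ppt (0.26, 0.27, 0.33 and 0.46). The count was 0 without tank 9, 733 without tank 3, 2231 without tank 8, 0 in a fit of day 6 alone and 515 with the visceral covariate. Without the libraries that stand apart, chosen by their liver level, only tank 4 is left at 30 ppt, so that fit cannot weigh the difference. For 20 v 30 ppt on day 6 edgeR called 0 genes (4535 at unadjusted p < 0.05; smallest p tcf19, −2.93 ± 0.54), DESeq2 418, and edgeR 1940 without tank 4. For 10 v 20 ppt it called 0 (416 at unadjusted p < 0.05), as did DESeq2.

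On day 15 larvae at 20 ppt had less RNA of liver and gut genes and of some complement genes than larvae at 30 ppt. They had more RNA of some heart and muscle progenitor genes. The glycogen genes ppp1r3g (−4.42 ± 1.27) and gys2 (−3.94 ± 1.21), the sterol transporter abcg5 (−4.16 ± 1.19), mamdc4 (−4.07 ± 1.11), the complement genes c8g (−3.76 ± 0.91) and c5 (−3.63 ± 1.11) and the clotting genes serpind1 (−3.71 ± 1.14) and f2 (−3.41 ± 1.0) were lower. So were fabp1 (−2.1 ± 0.36), slc5a1 (−2.86 ± 0.70) and apoa4 (−2.67 ± 0.71) of the intestine. Lower too were g6pc (−2.25 ± 0.57) and hk1 (−1.06 ± 0.26) of glucose metabolism, slc9a3 (−1.94 ± 0.56), cftr (−1.86 ± 0.59), sgk2 (−3.03 ± 0.73) and csad (−2.13 ± 0.59) of ion and osmolyte handling, evpl (−2.34 ± 0.57) and ppl (−1.81 ± 0.47) of skin, and ocln of tight junctions (−1.72 ± 0.50). Higher at 20 ppt were the cardiac genes myl7 (2.75 ± 0.78) and tnnt2 (2.02 ± 0.60), mag of myelin (2.24 ± 0.50), lama1 (1.74 ± 0.40), cldn19 (1.35 ± 0.29) and the muscle progenitor genes pax3 (1.46 ± 0.32), pax7 (1.21 ± 0.29) and myf5 (1.64 ± 0.49).

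edgeR called 1229 genes (244 higher and 985 lower at 20 ppt, 3 tanks each). The intestine list had 6 lower of 12 (12 adjusted over the list alone, median log2 −2.54, camera adjusted p = 2.41e-08) and liver 3 lower of 15 (14, −3.12, 2.41e-08). Innate immunity, which shares hpx with the liver list and holds complement genes, had 5 lower of 25 (9, −0.81, 0.000175). Carbohydrate metabolism had 4 lower of 17 (6, −0.70, 5.3e-05), ion transport 3 lower of 16 (6, −0.62, 0.0412) and osmolytes 5 lower of 15 (5, −0.11, 0.0412). Skin had 2 lower of 10 (7, −1.0, 0.00111), myogenic regulators 3 higher of 10 (4, 0.82, 0.00232) and slow and cardiac muscle 2 higher of 6 (4, 1.6, 0.00271). These are 9 of the 19 lists that camera called, and with an estimated correlation their adjusted p was 0.106 to 0.373. Liver levels were −1.56 and −1.38 and intestine levels −1.48 and −2.17 in tanks 2 and 7 at 20 ppt, against 1.06 and −0.55 in tank 1 and 1.09 to 3.36 and 0.44 to 1.85 at 30 ppt. The count was 145, 172, 198 and 482 without tanks 2, 7, 9 and 4, 1947 without tank 8, 720 without scaling factors and 3461 with the visceral covariate. It was 0 in a fit of day 15 alone. Leaving out the libraries that stand apart keeps only tank 1 at 20 ppt. These libraries were chosen by their liver level, which is part of the difference, so that fit cannot weigh it.

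Against larvae at 20 ppt, those at 10 ppt on day 15 had more RNA of gut genes and of some liver genes. The 2 comparisons share the 3 libraries at 20 ppt, so they are not independent. Higher at 10 ppt were abcg8 (4.74 ± 1.0), abcg5 (4.62 ± 1.19), c5 (4.26 ± 1.13), and tmprss15, which activates trypsinogen (3.78 ± 0.77). Higher too were the bile salt pump abcb11 (3.74 ± 0.95), c8g (3.12 ± 0.91), ehhadh (2.15 ± 0.39), slc5a1 (2.67 ± 0.70) and fabp1 (1.42 ± 0.36). So were evpl (2.43 ± 0.57) and ppl (2.09 ± 0.47), csad (2.56 ± 0.60) and cdo1 (1.34 ± 0.33), bfsp2 (2.92 ± 0.81), the glucocorticoid receptor nr3c1 (1.0 ± 0.23) and the prolactin receptor prlr (0.96 ± 0.26). Lower were otogl (−2.57 ± 0.80), adgrd2 (−2.35 ± 0.61), slc1a3 (−2.12 ± 0.54), cilp (−2.0 ± 0.59), pax3 (−1.83 ± 0.33) and cldn19 (−1.02 ± 0.29). edgeR called 1119 genes (866 higher and 253 lower at 10 ppt, 3 tanks each). The intestine list had 6 higher of 12 (12 adjusted over the list alone, median log2 2.55, camera adjusted p = 1.15e-07) and liver 0 of 15 (13, 2.91, 3.04e-05). Skin had 3 higher of 10 (6, 0.000818), endocrine axes 2 higher of 16 (6, 0.000818) and lens crystallins 2 higher of 5 (5, 2.16, 0.000752). These are 5 of the 13 lists that camera called, and their adjusted p with an estimated correlation was 0.291 to 0.472. Tank 6 at 10 ppt was itself low, with a liver level of −0.33 and an intestine level of −0.52. The count was 26 and 97 without tanks 2 and 7, 1693 with DESeq2 and 292 with voom and the tank as a random block. It was 629 without scaling factors, 5084 with the visceral covariate and 0 in a fit of day 15 alone. Without the libraries that stand apart, chosen by their liver level, only tank 1 is left at 20 ppt, so that fit cannot weigh the difference.

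On day 24 larvae at 10 ppt had less RNA of liver, gut, pancreas and lipid genes than larvae at 20 ppt, and more of neural genes. Lower were the lipid transfer protein cetp (−6.19 ± 1.80), the complement regulator cfp (−6.06 ± 1.76) and the gluconeogenic genes pck1 (−5.78 ± 1.38) and g6pc (−3.39 ± 0.73). So were abcg8 (−5.40 ± 1.28), the clotting genes fgb (−5.36 ± 1.55), serpind1 (−5.36 ± 1.53) and f2 (−4.93 ± 1.33), and c5 (−4.80 ± 1.41). pck1 was at 11.3 ± 0.757 CPM at 10 ppt and 623 ± 469 CPM at 20 ppt (n = 2 and 2). slc5a1 (−3.74 ± 0.89) and apoa4 (−3.79 ± 0.92) of the intestine, and ctrl (−3.64 ± 1.15) and cpa1 (−3.19 ± 1.09) of the pancreas were lower. So were srebf1 (−1.63 ± 0.24), fasn (−1.82 ± 0.41) and acads (−1.46 ± 0.40) of lipid metabolism, and cdo1 (−1.83 ± 0.41) and sgk1 (−1.16 ± 0.38) of the osmolyte list. Higher were mbp of myelin (3.06 ± 0.71), fosb (2.51 ± 0.68), npy (2.44 ± 0.73), sncb (2.34 ± 0.69) and slc17a6 (1.94 ± 0.58).

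edgeR called 3016 genes (1343 higher and 1673 lower at 10 ppt, 2 tanks each). Liver had 11 lower of 15 (13 adjusted over the list alone, median log2 −4.47, camera adjusted p = 2.01e-06), intestine 9 lower of 12 (11, −3.69, 5.37e-06) and pancreas 2 lower of 3 (3, −3.19, 0.0256). Fatty acid oxidation had 9 lower of 23 (15, −0.97, 2.01e-06), fatty acid synthesis 5 lower of 12 (6, −1.06, 0.000169) and innate immunity 9 lower of 25 (11, −1.56, 4.9e-05). Innate immunity shares hpx with the liver list and holds complement genes, so its call was not separated from that of liver. Carbohydrate metabolism had 8 lower of 17 (11, −1.2, 0.00053), osmolytes 7 lower of 15 (8 lower and 1 higher, −1.16, 0.00462) and the neural list 7 higher of 23 (13, 1.16, 5.37e-06). These are 9 of the 11 lists that camera called, and with an estimated correlation the adjusted p was 0.267 for fatty acid synthesis and 0.342 for the other 8. Liver levels were −0.71 and −0.26 in the 2 tanks at 10 ppt and 3.63 and 3.44 in the 2 at 20 ppt, and −0.51, 1.5 and 2.88 at 30 ppt. The count was 0 without tank 5, 115 without tank 6, 1146 without tank 7, 3 with the visceral covariate and 0 in a fit of day 24 alone. With the covariate ctrl, cpa1 and c5 turned to 0.09, 0.29 and 0.34. For ctrl and cpa1 this was largely built in, since they are members of the pancreas list that enters the covariate. c5 is in none of the lists of the covariate. But all of these lists are part of the difference, with mean intestine levels of −1.24 against 1.99 and pancreas levels of 2.46 against 5.44. The fall to 3 calls was thus largely built in too, and the fit with the covariate cannot weigh the difference. fbxo32 was called lower at 10 ppt (−5.14 ± 1.3) and higher when tank 7 was left out (0.32). For 20 v 30 ppt on day 24, 8 genes were higher at 20 ppt, among them the lipase lipg (1.29 ± 0.18), pnp of purine salvage (1.76 ± 0.34), plaa (1.22 ± 0.22), ciapin1 (1.01 ± 0.19) and retreg1 (2.92 ± 0.59), the last only through tank 7 (−0.33 without it). That count ran from 1 without tank 8 or tank 9 to 224 without tank 1, and was 0 in a fit of day 24 alone.

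Over tank sums of days 18, 20 and 24 the tanks at 10 ppt had more crystallin RNA than those at 20 ppt, mostly through day 24. Lens levels at 10 and 20 ppt were −0.66 and −0.83 against −3.25 and −2.25 on day 24, −3.43 and −3.87 against −3.15 and −3.31 on day 18, and −3.3 and −2.82 against −2.82 and −4.59 on day 20. Both libraries at 10 ppt on day 24 stand apart by their liver level. crybb1 (1.14 ± 0.15), cryba4 (1.11 ± 0.14), crygn (1.06 ± 0.15), cryba2 (1.01 ± 0.13) and the myelin gene mbp (1.75 ± 0.24) were higher. Lower were fbxo32 (−4.19 ± 0.52), mafk (−1.56 ± 0.24), the amino acid enzymes tat (−1.55 ± 0.20), got1 (−1.07 ± 0.15) and kmo (−1.05 ± 0.15) and gys2 of liver glycogen (−1.27 ± 0.19). edgeR called 71 genes (40 higher and 31 lower, 2 tanks each), with lens crystallins 3 higher of 5 (5 adjusted over the list alone, median log2 1.01, camera adjusted p = 7.01e-07, adjusted p = 0.523 with an estimated correlation), 1 of 14 lists that camera called. DESeq2 called 948, limma on tank means 198, edgeR without scaling factors 239 and libraries as replicates 20. The count was 13, 8 and 5 without tanks 1, 5 and 6 and 0 without tank 7 or tank 9. For 10 v 30 and 20 v 30 ppt edgeR called 0 genes (1606 and 1592 at unadjusted p < 0.05) and DESeq2 108 and 188. The smallest p values there were those of LOC111239098 (−3.58 ± 0.33) and LOC111230176 (−1.93 ± 0.21).

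The salinity effect depended on the day for 515 genes (edgeR F test of 12 interaction terms, adjusted p < 0.05, 57 libraries; 3167 at unadjusted p < 0.05). Named genes with the smallest p were lipg, the peroxisomal gene ehhadh, anks4b of microvilli, the purine gene gda, acmsd of tryptophan breakdown, asah2 and slc5a1 (adjusted p = 0.00905 to 0.0106). DESeq2 called 1761 genes, the fit with a replicate block 272, voom 40 and limma on the variance-stabilised values 190. The count was 2 without tank 5, 0 without tank 2 or tank 9 and 31 without tank 1.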

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

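The test of the difference between days, the choice of lists and bounds for days 15 and 24, the tests by age and eye genes and the splits of the libraries were chosen only after the results were seen. The thinning tests and the test for a library of another day were written before theirs. 515 genes stood out because a test showed that their salinity effect differed between days. Of 30 splits of the libraries the real one called the most genes (515, highest other 64). No higher rank is possible with 30 splits, so this argues against chance without excluding it. The count also fell when some single tanks were left out. The 10 v 20 ppt effect differed between days 24 and 15 for 2036 genes (edgeR, adjusted p < 0.05), with 1682 lower and 354 higher on day 24. Among them were got1 (difference −3.85 ± 0.58, 1.31 on day 15 and −2.54 on day 24), g6pc (−5.99 ± 0.94), xdh (−6.25 ± 1.0) and abcg8 (−10.14 ± 1.63). 312 genes were called on both days, 299 of them in opposite directions, where independent calls would overlap in 167. The 2 comparisons share no libraries, but both directions rest on libraries that stand apart, tanks 2 and 7 at 20 ppt on day 15 and both tanks at 10 ppt on day 24. The counts of the 2 days, 1119 and 3016, were 26 without tank 2 and 0 without tank 5, and 0 in fits of 1 day alone.

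On day 6, 95.5% of the genes called between 10 and 30 ppt differed in the direction of age (80% of all tested genes), as if tanks 8 and 9 at 30 ppt were further developed. That direction was taken from 20 ppt on days 18 and 20 against day 3, where mean liver levels were 3.04 and 3.32 against 0.93. Tanks 8 and 9 were also high, with 2.3 and 2.16. A larger share of liver and gut tissue could thus give the same direction. The 95.5% does not separate it from age, and both stay open. Eye genes, which rise later, do not decide on age either. The higher of the 2 eye levels was −0.20 (tank 9 −0.33), within the −0.73 to 0.05 of the tanks at 10 and 20 ppt on day 6. Tanks 2 and 7 on day 15, with −0.18 and 0.02, lay in that range too. A swap of the day 6 and day 12 libraries of tank 8 would not be the whole cause, since 2231 genes were called without tank 8. Against a swap goes the day 6 eye level of tank 8, which lay in the day 6 range. It was below the 0.34 to 0.77 of the tanks at 10 and 20 ppt on day 12. Later libraries can lie in the day 6 range too, so this is weak evidence on tank 8. Other values go with a swap: its day 12 eye level of 0.03 also lay in the day 6 range, and its bone level (1.41 on day 6, 0.48 on day 12) was higher on the earlier day. Depth is argued against, because 4694 genes were called after thinning to 6.32 M counts. A salinity effect stays open, as 10 splits are too few to exclude chance (5169 and 70). Tank 4, also at 30 ppt, does not decide it. Its osmolyte and intestine levels (0.35 and 0.39) lie above the 10 ppt tanks (at most −0.11 and −0.26), but near tank 2 at 20 ppt (0.27 and 0.33) and below tanks 8 and 9 (0.63 and 1.13, 1.15 and 2.14).

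On day 15 the lower liver and gut genes at 20 ppt could come from younger larvae. The fast muscle list, which rose from day 12 to day 15 (median 1.2), argues against it. Its median was 0.29 at 20 against 30 ppt, and its levels of 1.35 to 2.43 at 20 ppt lay above the highest of day 12 (1.02). Levels are relative to the library total, so less liver and gut RNA could also raise this list, which limits the argument. Libraries low in liver RNA differed in it: tank 7 on day 6 had 1.43, and tanks 2 and 8 on day 12 had 0.54 and −0.01. Depth is argued against by 967 genes called after thinning to 6.46 M. A smaller share of liver and gut tissue stays open, since the lower skin list (median −1.0) has tank 8 at 30 ppt (−0.80) within the 20 ppt levels (−0.94 to −0.17). Which tanks carry the difference is shown by the libraries: tanks 2 and 7 have liver levels of −1.56 and −1.38 and tank 1 has 1.06. Whether salinity, tissue share, feeding state or the fish drawn is the cause stays open, and 10 splits are too few to exclude chance (1229 and 930 for 20 v 30 ppt, 1119 and 20 for 10 v 20 ppt). For 10 v 30 ppt, 3 of the 10 splits called as many genes as the real 8, and one called 2897, with tanks 3, 4 and 9 (liver levels 3.67, 2.97 and 3.36) on one side, which points to a structure of the samples other than salinity.

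On day 24 the lower liver, gut and pancreas genes at 10 ppt might reflect age. The fast muscle median of 0.20 does not decide this, since that list hardly moved from day 20 to day 24 (median 0.11), and the gastric list (median −2.47) goes the way of younger larvae. Depth is argued against by 2897 genes called after thinning to 7.18 M. A smaller share of liver and gut tissue stays open, since the lower bone and cartilage list (median −0.57) has tank 7 at 20 ppt (1.56) within the 10 ppt levels (1.5 and 1.95). Tank 8 at 30 ppt, with a liver level of −0.51, is as low as the 2 tanks at 10 ppt. Whether salinity, age, tissue share or the fish drawn is the cause stays open.

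Between days, 24 splits that swap the days within tanks called at most 1518 genes for day 6 v 3 (real 4849), 717 for 15 v 12 (3213), 6423 for 18 v 15 (8661), 8026 for 24 v 20 (8183) and 10291 for 24 v 3 (11615). For each of these only the real split was as large, the best rank that 24 splits allow. That argues against chance for each count but does not exclude it. The margin was small for 24 v 20, but there the highest other split swapped tanks 4, 5, 6, 7, 8 and 9. Apart from the sign it differs from the real split in tank 1 only. For 6 v 3, 18 v 15 and 24 v 3 the highest other split swapped only tank 4, tank 9 and tank 8. Such splits stay close to the real one, so their margins do not measure chance. In 24 splits that permute the days within a salinity the highest other counts were 505, 1400, 591, 8026 and 7132, and the median of the others was 0 for each. For day 20 v 18 the other splits called 0 genes and the real one 3, a count too small to rest on, since it was 0 with the replicate block and 0 to 1 without a tank. For day 12 v 6, 2 of 24 splits of either kind were as large (2791 real, 6076 and 3277 highest other), so chance cannot be excluded, and a split with more than the real count points to a structure of the samples. Within 30 ppt 10 splits are too few, with real and highest other counts of 5638 and 0, 688 and 3547, 1743 and 3966, 763 and 0, 2438 and 0, and 6686 and 331 for day 6 v 3, 12 v 6, 15 v 12, 18 v 15, 24 v 20 and 24 v 3.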

How the results depend on the processing

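Day counts kept their order of size under most tools and filters, whereas salinity counts within a day depended on single tanks. With 2 or 3 tanks per group, changes of 2-fold are often missed. A tank left out can leave a group with 1 library, which is then assumed to vary like the other groups. For the changes below the cause was not tested, except that fits of 1 day and fits without a tank rest on fewer libraries. Fits of 1 day also use only the spread of that day, and the spread differed between days. At 30 ppt the SD of the liver level was 1.52, 1.22 and 1.71 on days 6, 15 and 24. It was 0.16 and 0.22 on days 18 and 20. The pooled fit may thus call too many genes between salinities on days 6, 15 and 24. Of 5440 values of 303 named genes under alternatives chosen before the data were examined, 4685 kept direction and call, 736 lost the call, 17 gained it and 2 reversed. In fits of 1 day alone 116 of 117 values lost the call. Of 553 values under alternatives chosen after the data were seen 329 stayed, 221 lost the call and 3 reversed.

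With DESeq2 10 v 30 ppt had 4, 22, 1, 3 and 17 calls on days 3, 15, 18, 20 and 24, 20 v 30 ppt had 2, 418, 1 and 37 on days 3, 6, 20 and 24, and 10 v 20 ppt had 1, 1693 and 2 on days 3, 15 and 20. Day 20 v 18 had 6, and within 30 ppt day 12 v 6 had 1165, 18 v 15 had 1991 and 20 v 18 had 1. Early tank sums had 23, 1 and 3 (trend 30), late ones 108, 188 and 948, and the interaction 1761. On variance-stabilised values limma called 1, 0 and 3 for 10 v 30 ppt on days 3, 20 and 24, 1 and 2 for 20 v 30 ppt on days 6 and 24, 0 for 10 v 20 ppt on day 20, 1 for day 20 v 18 and 190 for the interaction. With voom and a random tank block 10 v 30 ppt had 0 on days 15 and 20, 10 v 20 ppt 292 and 0 on days 15 and 20, and the interaction 40.

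In fits of 1 day alone 10 v 30 ppt had 0 calls on days 6, 15, 20 and 24, 20 v 30 ppt 0 on days 15 and 24, and 10 v 20 ppt 0, 5, 0 and 0 on days 15, 18, 20 and 24. Without a scaling factor 20 v 30 ppt had 2, 720 and 2 on days 6, 15 and 24, 10 v 20 ppt 629 and 0 on days 15 and 20, and late tank sums 4 for 10 v 30 and 239 for 10 v 20 ppt. The stricter filter gave 1 for 20 v 30 ppt on day 6 and 0 for day 20 v 18, RLE factors 0 for day 20 v 18, and no filter 17 and 116 for late 10 v 30 and 10 v 20 ppt. Libraries as replicates gave 1 for early 10 v 30 ppt, 2 for the trend, and 1 and 20 for late 10 v 30 and 10 v 20 ppt, and tank means 1 and 198.

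Libraries of the same tank on different days did not deviate together (median correlation per tank −0.07 to 0.09). With the tank as a replicate block day 20 v 18 had 0 calls, day 18 v 15 within 30 ppt 189 and the interaction 272, and no other count moved by more than 1.5 times.

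Chosen after the data were seen, the visceral covariate gave 515 and 0 for 10 v 30 ppt on days 6 and 24, 3461 for 20 v 30 ppt on day 15, and 5084 and 3 for 10 v 20 ppt on days 15 and 24. Days 15 v 12, 18 v 15, 20 v 18, 24 v 20 and 24 v 3 had 5176, 542, 1, 3641 and 7052, within 30 ppt 6 v 3, 15 v 12, 18 v 15, 24 v 20 and 24 v 3 had 997, 1077, 1545, 934 and 2735, and the interaction 176. On day 24, 10 v 20 ppt, ctrl, cpa1 and c5 turned to 0.09, 0.29 and 0.34. As pancreas list members ctrl and cpa1 are part of the covariate, so their change was largely built in. Where the lists of the covariate are part of a difference, as between salinities on days 6, 15 and 24, its counts cannot weigh that difference. Without the libraries that stand apart 10 v 30 ppt had 0 and 1 on days 6 and 15, 20 v 30 ppt 2 and 1 on days 15 and 24, and 10 v 20 ppt 0 on days 15 and 20. Days 6 v 3, 12 v 6, 15 v 12, 18 v 15, 20 v 18 and 24 v 20 had 1960, 4437, 597, 5175, 0 and 2728, and within 30 ppt all but 20 v 18 had 12, 35, 60, 1979 and 638. The counts within 30 ppt are those of the steps between sampled days. The libraries left out include none at 30 ppt on days 15 and 18, so the step 18 v 15 within 30 ppt kept its own libraries. This setting leaves only tank 4 at 30 ppt on day 6 and only tank 1 at 20 ppt on day 15. For 10 v 30 and 10 v 20 ppt on day 24 and for the interaction it gives no value, since no library at 10 ppt is left on day 24.

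Leaving out 1 tank, 10 v 30 ppt ran from 0 to 4 on day 3, 0 to 7323 on day 6, 0 to 1 on day 12, 0 to 76 on day 15, 0 to 2 on day 20 and 0 to 2 on day 24. 20 v 30 ppt ran from 0 to 25 on day 3, 0 to 1940 on day 6, 145 to 1947 on day 15, 0 to 1 on day 18 and 1 to 224 on day 24. 10 v 20 ppt ran from 0 to 15 on day 3, 26 to 1693 on day 15, 0 to 5 on day 20 and 0 to 3268 on day 24. Days ran from 2692 to 5179 (6 v 3), 1811 to 2833 (12 v 6), 1839 to 3063 (15 v 12), 4457 to 9778 (18 v 15), 0 to 1 (20 v 18) and 3728 to 8479 (24 v 20). Within 30 ppt they ran from 209 to 6256, 58 to 889, 0 to 2149, 0 to 1469, 0 to 3054 (24 v 20) and 1901 to 7090 (24 v 3). Early 10 v 30 ppt ran from 0 to 2, the trend 0 to 3, late 10 v 30 ppt 0 to 4, 20 v 30 ppt 0 to 192, 10 v 20 ppt 0 to 460 and the interaction 0 to 731. On day 24 retreg1 (20 v 30 ppt) ran from −0.33 to 3.91 and fbxo32 (10 v 20 ppt) from −6.2 to 0.32.

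With the preset correlation camera also called 5 lists for 10 v 30 ppt on day 15, 12 for 20 v 30 ppt on day 24, and 3 and 12 for late 10 v 30 and 20 v 30 ppt. With an estimated correlation it called 0 lists in all 18 comparisons. With exact symbols it called 3 lists for day 15 v 12, 4 for day 24 v 3 and 1 for late 10 v 30 ppt.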

Other observations

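Over tank sums of days 18, 20 and 24 lens crystallins were also higher at 10 than at 30 ppt, mostly through day 24 (mean levels −0.75 and −2.56, against −3.06 and −3.81 on day 20 and −3.65 and −3.27 on day 18), with 0 of 5 called and 5 higher when adjusted over the list alone (median log2 0.93, camera adjusted p = 5.37e-11, adjusted p = 0.388 with an estimated correlation). On day 20 the gastric list level of tank 5 at 10 ppt was 0.05, and the other 6 libraries of that day had 3.23 to 4.51. LOC111230176, singled out after its values were seen, was also lower at 10 than at 30 ppt on day 18 (−2.93 ± 0.62, edgeR adjusted p = 0.529, 2 and 3 tanks).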
